A study of Mus musculus with 3 samples.

How the data were processed

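Mouse dentate gyrus was dissociated and profiled by droplet-based single-cell RNA sequencing, which counts unique molecular identifiers (UMIs) per gene and cell barcode. Per the labels, the 3 libraries were 10x Genomics Chromium 3' version 2 libraries, the tissue was digested with trypsin, and no cell sort was described. Per the submitters' processing notes, Cell Ranger 2.1.1 and Seurat 3.1.0 were used with the genome build GRCm38. The aligner, the annotation release and the rule by which barcodes were called as cells are not given in the sources used here. The authors deposited 1 table of raw UMI counts per library, with gene symbols and no other gene identifier. The deposited counts were whole numbers whose totals differed between barcodes, and no gene was listed with UMIs in fewer than 3 barcodes of its library. A gene missing from a table is therefore reported as not listed rather than as 0. The tables listed 13440 genes for control, 15052 for runner and 13128 for aged, with 15535 in at least 1 table and 12324 in all 3.

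Barcodes with at least 200 detected genes and under 10% mitochondrially encoded UMIs were used, after removal of Scrublet doublet calls made per library at an expected rate of 0.05. The filter removed 53 control, 369 runner and 151 aged barcodes for too few genes, and 1789, 1990 and 1877 barcodes had at least 10% mitochondrially encoded UMIs. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, chosen within 20 expression bins among genes seen in at least 5 cells, were scaled, limited to 10 and reduced to 30 principal components. The 3 libraries were clustered together without batch correction, on a shared-neighbour graph of 15 neighbours with the Leiden method at resolution 1.0 and seed 1. The tools were Scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, SciPy 1.17.1, NumPy 2.4.6, pandas 2.3.3 and Python 3.11.15.

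Clusters were named from 22 lists of cell type markers fixed before the data were examined, and every name means "like" that type. For each cluster, CPM plus 20 was divided by the median of the other clusters, and its 10 leading genes were taken among those detected in at least 25% of its cells. The cluster took the name of the list with the most markers among these genes, if at least 3 markers of that list were detected at that percentage and at 2-fold or more, and if the mean log2 fold of the list was at least 1. A cluster with at least 50% of cells carrying 3 or more proliferation genes was named cycling. These naming thresholds were set after seeing the data. A first rule, by the highest mean fold and a detection limit of 10%, left endothelial-like, shallow microglia-like and newly formed oligodendrocyte clusters unnamed. Pyramidal neuron names were counted with granule neurons and newly formed oligodendrocyte names with oligodendrocytes, also decided after seeing the data. No cluster took the name of neural stem cells, intermediate progenitors, GABAergic neurons, mural cells, vascular leptomeningeal cells, ependymal cells, choroid plexus cells, T or NK cells, B cells, monocytes or neutrophils, or erythroid cells. Astrocyte-like cells were reclustered alone with 20 principal components at resolution 0.6.

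Shares of cells are given with exact Clopper-Pearson 95% intervals, differences between shares with Newcombe intervals, and folds between shares with exact intervals. For gene levels, UMIs were summed over the cells of a class in a library and divided by the sum over all genes to give CPM, the usual per-library scaling of counts. CPM ratios carry exact conditional binomial 95% intervals. With 1 library per group, no test between groups was run, and no gene was called changed. A cell was counted as cycling when at least 3 of 24 proliferation core genes were detected, and this was repeated after thinning each cell to 1000 UMIs, a depth chosen after seeing the data. The lineage of cycling cells was called from marker lists by a rule also chosen after seeing the data.

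The 17 gene lists fixed before the data were examined were proliferation core, S phase and licensing, BMP and Notch quiescence, astrocyte transport and coupling, reactive astrocyte, interferon and MHC class I, homeostatic microglia, disease-associated microglia, myelin, cholesterol synthesis, glycolysis, dissociation stress, growth factors and their receptors, ribosomal protein, oxidative phosphorylation, mitochondrially encoded, and a sex-linked check. A list was described in a class by the median log2 CPM ratio of its members with at least 20 UMIs in the 2 libraries, after adding 0.5 counts. Its percentile among 10000 random lists of the same size, matched on expression in 10 bins, is a description of these libraries and not a test. The 95% range of a median comes from 200 Poisson draws of the counts. Cells were kept only under 10% mitochondrially encoded UMIs, so the filter limits the values of the mitochondrially encoded list in every class. Lists with fewer than 5 such members, and classes with fewer than 25 cells in a library, were not described, limits set after seeing the data. The neural stem cell marker list was added for astrocyte-like cells after counts of its members had been seen. A list of 10 dendritically localised mRNAs and 1 of 8 nuclear-retained RNAs were used for barcodes outside the comparisons. Camk2a on the first of these is also a marker on the pyramidal neuron list.

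Named genes followed a rule fixed before the data were examined. In astrocyte-like cells these were the 12 highest and 12 lowest genes of each comparison with at least 50 UMIs, ranked by the interval bound nearest to 1, without mitochondrial, ribosomal, predicted or sex-linked genes and without markers of another class. In other classes with at least 100 cells in both libraries, which only microglia-like cells met, the 3 highest and 3 lowest were taken. Members of each list with the most UMIs were added, as were Gfap, Vim, Nes, Hopx, Sox2, Id4, Mki67, Dcx and Aqp4. Some genes that the rule gave are not reported here and were left out of the gene plot and of the alternatives for single genes. Gene positions come from the GENCODE annotation of GRCm38 and were matched by symbol.

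The calculation of the counting intervals was checked on simulated data with the depths of these libraries. The counts were drawn with Poisson counting error alone, the error that the intervals assume, so coverage near the nominal level was built in. Spread between cells, clusters or mice was not simulated, so the shares below do not show how well the intervals hold for these libraries. For runner against control, the intervals held the true fold for 97.3% of 1989 genes in astrocyte-like cells and 96.7% of 5126 in microglia-like cells. For aged against control, the shares were 96.4% of 1154 and 96.4% of 4041 genes. Among simulated genes without a difference, 2.79% and 3.56% of intervals in astrocyte-like cells excluded 1, for runner and aged respectively, and 3.31% and 3.46% in microglia-like cells. A simulated 2-fold difference gave an interval above 1 for 62.5% (runner) and 72.5% (aged) of genes in astrocyte-like cells, and for 77.5% and 67.5% in microglia-like cells. A 1.5-fold difference did so for between 30% and 50% of genes. Simulated lists of 15 genes at 1.5-fold reached percentile 100 in 3 of the 4 comparisons and 89.2 in aged astrocyte-like cells, and lists of 15 unchanged genes lay between percentile 5.4 and 66.8.

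Alternatives fixed before the data were examined were a limit of 1000 UMIs per cell, no filter, doublet calls kept, resolutions 0.5 and 2.0, each library clustered by itself, 2 or 5 proliferation genes, thinned cells, median-of-ratios size factors, totals without mitochondrial and ribosomal protein genes, the mean of the cells' own CPM, list members with at least 5 or 100 UMIs, the other library as the reference, and subcluster resolutions 0.3 and 1.0. Alternatives chosen after seeing the data were a mitochondrial limit of 30%, no filter for cycling cells, the microglia-like class without its shallow cluster, subclustering without the dissociation stress list, the neural stem cell marker list, and naming by the first rule. Scaling alternatives moved the median log2 ratio of all genes by between -0.099 and 0.088 over the classes and comparisons.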

Results

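The dentate gyrus is the hippocampal region in which neural stem cells produce new granule neurons and astrocytes in adult mice. Dissociated dentate gyrus was profiled in 3 single-cell libraries, 1 per group: young mice in standard housing at 8 weeks (control), young mice with a running wheel for 12 days (runner), and mice without a wheel at 14 months (aged). The strain is given as hGFAP-eGFP in the sample labels, a reporter line for the astrocyte and stem cell gene GFAP, while the series description calls the mice wild type and names the reporter for the aged mice alone. The number of mice behind each library is not given in the sources used here. The title of the series concerns the formation of astrocytes by proliferating neural stem cells and local astrocytes. Runner against control asks how these cells and their progeny differed with running, and aged against control asks the same for age.

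The tables held 2356 control, 3328 runner and 2421 aged barcodes with 2330698, 3808360 and 2537567 UMIs in total. Mitochondrially encoded transcripts took a median of 36.6%, 42.9% and 46.3% of the UMIs of a barcode. With at least 200 genes and under 10% mitochondrial UMIs required, 21.8%, 29.1% and 16.2% of barcodes passed. The comparisons rest on 512 control, 963 runner and 391 aged cells with medians of 1460, 1747 and 1409 UMIs per cell. With 1 library per group there was no replicate check, so "higher" and "lower" describe these libraries, and the 95% intervals in parentheses cover counting error alone. Both comparisons use the same control library, so a value that was off in control would move both the same way.

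Microglia-like cells, the resident macrophages of the brain, were the most common class in each library. Astrocyte-like, neuroblast-like, granule-neuron-like, oligodendrocyte-like, oligodendrocyte-precursor-like and Cajal-Retzius-like cells followed, with a few endothelial-like and perivascular-macrophage-like cells and 1 cluster of cycling cells. No cluster was named for neural stem cells or intermediate progenitors. Radial glia-like stem cells share most markers with astrocytes, so the astrocyte-like class covers astrocytes and any such stem cells that were sampled.

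**Figure D1:**
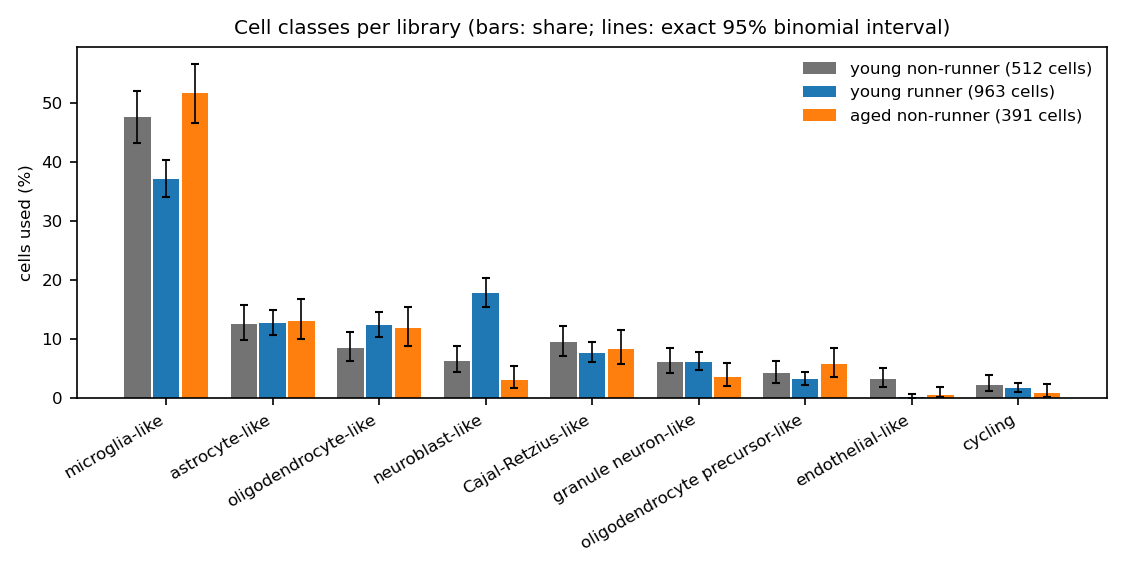
Share of the cells used (y axis, percent) in each of the main cell classes (x axis) for control, runner and aged, 1 library each; bars are shares, lines are exact 95% counting intervals, and perivascular-macrophage-like and unnamed cells are not drawn. Neuroblast-like cells stand at 6.25% in control, 17.8% in runner and 3.07% in aged, while astrocyte-like cells stand between 12.5% and 13%.

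In the runner library, neuroblast-like cells, the immature neurons that express Dcx and Sox11, made up a larger share than in control. They were 171 of 963 runner cells (17.8%, 15.4 to 20.3) and 32 of 512 control cells (6.25%, 4.31 to 8.71), a 2.84-fold difference (1.94 to 4.28) or 11.5 percentage points (8.16 to 14.6). The astrocyte-like share was 12.7% (10.6 to 14.9) in runner and 12.5% (9.76 to 15.7) in control, a difference of 0.169 points (-3.54 to 3.6). Microglia-like cells had a lower share in runner, 37.2% (34.1 to 40.3) against 47.7% (43.3 to 52.1), a difference of -10.5 points (-15.7 to -5.19). Granule-neuron-like cells were level at 6.02% and 6.05%.

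Of the remaining classes, oligodendrocyte-like cells were 12.4% of runner and 8.4% of control, higher by 3.96 points (0.621 to 7.02). Oligodendrocyte-precursor-like cells were 3.12% and 4.1%, and Cajal-Retzius-like cells, early-born neurons that secrete reelin, were 7.58% and 9.38%. Endothelial-like cells were 1 of 963 in runner and 16 of 512 in control, a difference of -3.02 points (-4.91 to -1.73). Perivascular-macrophage-like cells were 10 in runner and 1 in control. These shares hold for barcodes under 10% mitochondrial UMIs, a limit that a larger share of runner than of control barcodes passed. Without that filter the neuroblast-like share was 6.08% in runner and 3.14% in control. In that class, 22 of the 202 runner cells and 27 of the 74 control cells were then cycling cells.

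Dcx, Sox11, Neurod1 and Calb2 were also higher over all the runner cells used. They are among the markers of the neuroblast-like cluster, so they are not evidence independent of its share. Their gaps did not all match that of the share, and the gap of Calb2 was wider. Dcx, which encodes the microtubule-binding protein doublecortin (chromosome X, 143855842 to 143933311, minus strand, GRCm38), stood at 111 CPM (95.7 to 127) over the runner cells used and 36.3 (24.1 to 52.5) over the control cells. Sox11, a transcription factor of immature neurons, stood at 606 and 285 CPM, Neurod1 at 202 and 85.6, and Calb2, which encodes calretinin, at 364 and 35.0. These 4 genes were chosen for this reading after their values were seen. Eomes, a transcription factor of intermediate progenitors, was level at 19.1 and 18.2 CPM. Neurog2, on the same marker list, had 24 UMIs in 14 of the runner cells used and was not listed in control. The runner cells of the neuroblast-like class were deeper, with a median of 1979 UMIs against 1380, and 171 of the 215 cells of that cluster came from the runner library.

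No difference in cells with at least 3 proliferation core genes was detectable between runner and control at this depth and under the mitochondrial filter. Mki67 by itself was higher in runner. Such cells were 21 of 963 in runner (2.18%, 1.35 to 3.31) and 12 of 512 in control (2.34%, 1.22 to 4.06). Most of these cells formed a cluster of their own, so the 0 cycling cells in the astrocyte-like class of either library follow from the clustering and set no limit on cycling among astrocytes or stem cells. Mki67, the proliferation marker Ki-67 (chromosome 7, 135689784 to 135716361, minus strand), had 0 UMIs in that class in either library, with the same reservation. Over all cells used it was detected in 52 of 963 runner and 6 of 512 control cells, at 38.7 CPM (30.1 to 49.0) and 18.2 (9.93 to 30.5), and over all barcodes it stood at 19.7 (15.5 to 24.7) and 9.01 (5.58 to 13.8). The 52 runner cells with Mki67 outnumbered the 21 cycling cells, so some of them did not meet the rule of 3 genes. In control, 6 cells had Mki67 and 12 were cycling. Top2a, another proliferation gene, was level at 28.6 (21.3 to 37.7) and 28.5 (17.9 to 43.2) over the cells used. Neuroblast-like cells held 5 cycling cells of 171 in runner (2.92%, 0.956 to 6.69) and 0 of 32 in control. By marker genes, 4 of these 5 cells were astroglial and 1 was neurogenic.

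The separate cluster held 15 of the cycling cells in runner and 11 in control. Over all cycling cells used, the marker genes called 8 of 21 in runner and 5 of 12 in control microglial, 8 and 3 astroglial, and 4 and 3 neurogenic. With no filter, cycling cells were 25 of 3325 runner barcodes (0.752%, 0.487 to 1.11) and 27 of 2355 control barcodes (1.15%, 0.757 to 1.66). A smaller part of the control than of the runner cycling cells was thus left under the filter. Of the cycling cells without a filter, 8 of 25 in runner and 11 of 27 in control were astroglial. The astroglial call was also made for 29.1% of granule-neuron-like and 15.7% of Cajal-Retzius-like cells, and the neurogenic call for 6.8% and 19.0% of them, so neither call fixes the lineage of a single cell. After thinning to 1000 UMIs, cycling cells were 15 of 854 runner cells and 8 of 408 control cells. The cycling cells in the runner neuroblast-like class varied with the clustering resolution, with 0 at resolution 2.0 and 6.74% of the class at resolution 0.5.

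Within astrocyte-like cells, Gfap, the intermediate filament of astrocytes and stem cells, was higher in runner than in control. Gfap (chromosome 11, 102887336 to 102900912, minus strand) had 83 UMIs in 122 runner cells and 22 in 64 control cells, 477 against 253 CPM and a ratio of 1.88 (1.17 to 3.17). Over all cells used, Gfap was level, at 81.4 and 84.3 CPM. The highest genes by the interval were Hsp90b1, a chaperone of the endoplasmic reticulum, at a ratio of 3.2 (1.63 to 6.98), Cnn3, an actin-binding calponin, at 2.4 (1.47 to 4.1), and Ckb, brain creatine kinase, at 1.55 (1.3 to 1.84). Cd81 (1.4), Gpr37l1 (1.53), Tubb2a (2.09), Gnao1 (1.82), Aldoc (1.28), Phyhipl (2.03), Ndufab1 (1.89) and Tecr (1.51) completed the 12 highest genes, with every interval above 1.

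The lowest genes in runner astrocyte-like cells were led by the metallothioneins, metal-binding proteins induced by zinc and stress hormones. Mt2 stood at a ratio of 0.527 (0.461 to 0.601) and Mt1 at 0.656 (0.609 to 0.706). Ptn, the secreted growth factor pleiotrophin, stood at 0.756 (0.66 to 0.866). The respiratory chain genes Cox8a (0.7), Ndufa5 (0.568) and Ndufa4 (0.687) were among the 12 lowest, with Ptprs (0.419), Guk1 (0.413), Slirp (0.448), Chchd10 (0.623) and BC002163 (0.514). Cox8a was also lower in runner microglia-like cells (0.708, 0.624 to 0.804) and oligodendrocyte-like cells (0.745, 0.593 to 0.94). The genes named in astrocyte-like cells were not checked for a shift over the whole library, in either comparison. Of the stem cell genes chosen in advance, Hopx (1.17, 0.823 to 1.69), Sox2 (1.4, 0.826 to 2.46), Id4 (0.66, 0.393 to 1.12) and Vim (0.555, 0.203 to 1.54) had intervals that hold 1. Nes, an intermediate filament of stem cells, had 3 UMIs in runner and 1 in control (1.5, 0.12 to 78.6). Aqp4, the water channel of astrocytes, stood at 0.815 (0.564 to 1.19), and Dcx had 0 UMIs in both. Set against aged instead of control, runner Gfap, Gnao1 and Ptprs turned direction, with log2 ratios of -0.0836, -0.0229 and 0.205.

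**Figure D2:**
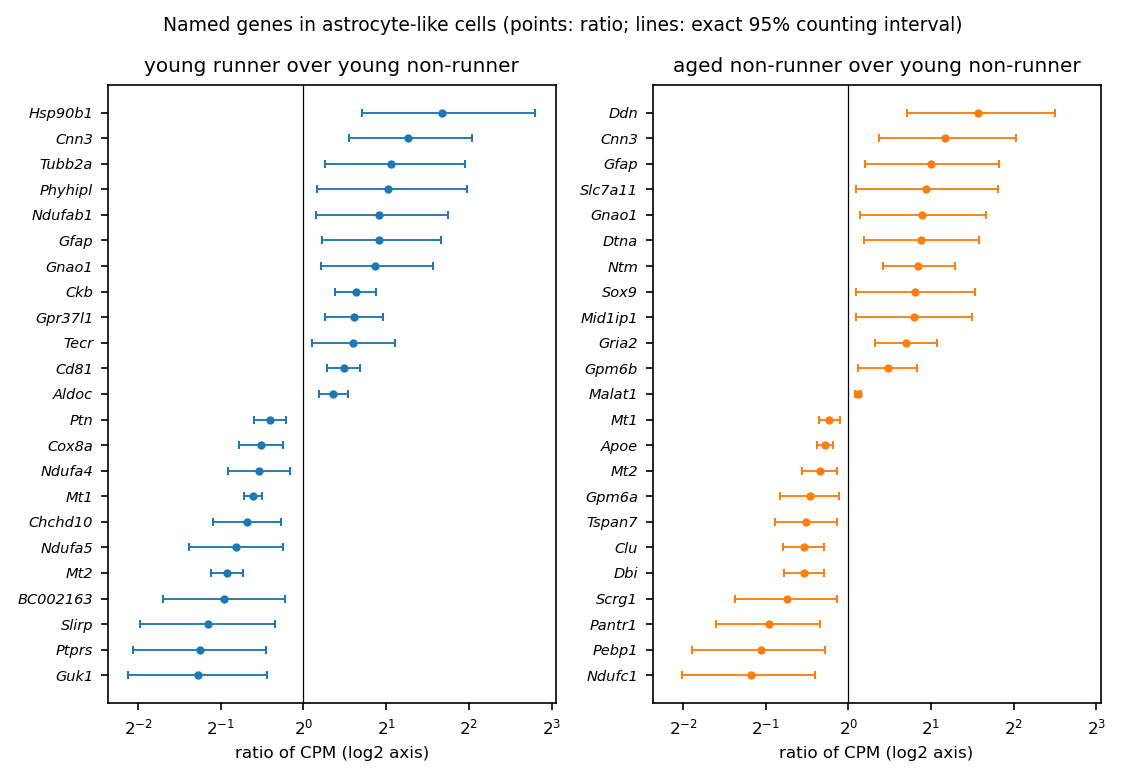
CPM ratio (x axis, log2-spaced) of the reported genes among the 12 highest and 12 lowest (y axis) in astrocyte-like cells for runner over control and aged over control, 1 library each; points are ratios and lines are exact 95% counting intervals. Gfap stands at 1.88 in runner and 2.0 in aged, and Mt2 at 0.527 and 0.787.

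Neural stem cell markers were higher as a list in runner astrocyte-like cells, as were genes of the dissociation stress list in the same cells. The stem cell list had a median log2 ratio of 0.70 (0.23 to 1.05) with 5 of 6 measured members higher, above 99.9% of random lists. It was added after counts of its members had been seen, so this is not independent evidence. Fabp7, the fatty acid-binding protein of radial glia (chromosome 10, 57784881 to 57788450, plus strand), stood at 2.0 (1.57 to 2.58), Thrsp at 1.78 (1.31 to 2.46), and Hes5, a Notch target, at 0.74 (0.525 to 1.05). The dissociation stress list, genes induced by tissue digestion, had a median of 0.42 (0.20 to 0.73) with 11 of 14 members higher, at percentile 99.0, with Fos at 1.41 (1.05 to 1.93) and Jun at 1.54 (1.1 to 2.18). In reclustering, the subcluster led by Fos, Junb and Jun, in which Hopx, Riiad1, Frzb and Thrsp were at least 2-fold higher, held 41 of 122 runner cells (33.6%, 25.3 to 42.7) and 13 of 64 control cells (20.3%, 11.3 to 32.2). The interval of that difference of 13.3 points holds 0 (-0.502 to 25.2), and the stress genes that lead the subcluster themselves differed between the libraries. At resolution 1.0 the difference was 16.6 points (2.62 to 28.5). Reclustered without the stress list, chosen after seeing the data, it was 14.3 (0.0403 to 26.7), though Junb, Fos and Jun still led that subcluster.

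Of the lists that describe astrocyte function, transport and coupling genes were nearly level in runner, with a median log2 ratio of 0.049 (-0.12 to 0.19) and Slc1a2, the main glutamate transporter, at a ratio of 1.04 (0.919 to 1.17). BMP and Notch quiescence genes had a median of 0.20 (-0.35 to 0.49) with 5 of 9 higher, and Id2 stood at 1.47 (1.05 to 2.09). Glycolysis genes had a median of 0.12 (-0.043 to 0.34) with 11 of 14 higher. Cholesterol synthesis genes were at 0.16 (-0.11 to 0.79), at percentile 51.1, and growth factors and their receptors at 0.15 (-0.15 to 0.44), where Sparc stood at 3.78 (2.16 to 7.15). The disease-associated microglia list, of which astrocytes also express Apoe, Cd63 and Cd9, was at 0.24 (0.094 to 0.60) with 6 of 8 higher and turned to -0.0141 with members down to 5 UMIs. Ribosomal protein genes were lower at -0.19 (-0.29 to -0.12), with 58 of 79 below control. Mitochondrially encoded genes were lower at -0.44 (-0.52 to -0.31), a value limited by the filter, which kept cells under 10% of such UMIs. Over all barcodes, of any class, their median share was higher in runner (42.9%) than in control (36.6%). Nuclear genes of oxidative phosphorylation were at -0.10 (-0.22 to -0.042), a direction that turned with aged as the reference (0.0712). The proliferation core, S phase, reactive astrocyte, interferon, homeostatic microglia and myelin lists had 3 or fewer measured members in these cells and were not described.

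Runner microglia-like cells had higher homeostatic genes than control, with a median log2 ratio of 0.16 (0.076 to 0.24), 10 of 15 members higher and percentile 95. The purinergic receptor P2ry12 stood at a ratio of 1.31 (1.23 to 1.41), while Cst3 stood at 0.814 (0.802 to 0.827). The homeostatic median was -0.0117 with aged as the reference. The disease-associated list was level at 0.018 (-0.086 to 0.24), or -0.14 with members down to 5 UMIs, with Ccl4 at 1.49 (1.39 to 1.59) and Fth1 at 0.86 (0.808 to 0.916). Interferon and MHC class I genes were at -0.065 (-0.28 to 0.14), with H2-D1 at 0.795 (0.704 to 0.897), and dissociation stress genes at -0.047 (-0.11 to 0.020). Glycolysis genes were at 0.26 (-0.082 to 0.35), S phase genes at 0.17 (-0.093 to 0.77), reactive astrocyte genes at 0.28 (-0.027 to 0.61), cholesterol synthesis genes at 0.11 (-0.69 to 0.57), myelin genes at -0.13 (-0.44 to 0.37) and oxidative phosphorylation genes at 0.028 (-0.083 to 0.078). Ribosomal protein genes were lower at -0.18 (-0.24 to -0.16) and mitochondrially encoded genes at -0.60 (-0.73 to -0.55), both below each of the random lists. The filter limits the mitochondrially encoded list and not the random lists, so its rank among them is no fair yardstick.

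The single genes furthest from control in runner microglia-like cells were Gdpd3 at a ratio of 13.6 (4.46 to 67.7, 66 against 3 UMIs), Gng10 at 4.69 (2.56 to 9.42) and Churc1 at 3.57 (2.49 to 5.27) on the high side. The low side included Ubb at 0.494 (0.451 to 0.541) and Actb at 0.611 (0.585 to 0.639). All 6 genes that the naming rule gave were shifted the same way in the cells outside the microglia-like class, for example Actb at 0.691 (0.655 to 0.728), and Ubb turned to a log2 ratio of 0.0156 with aged as the reference. Classes whose shares differed between the libraries were pooled outside the microglia-like class, which can also move these ratios. The makeup of the class differed: the largest of its 3 clusters held 57.0% of runner and 44.3% of control microglia-like cells, and a shallow cluster held 10.3% and 20.1%. Without the shallow cluster the difference in the microglia-like share was -4.75 points rather than -10.5.

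In the aged library, neuroblast-like cells made up a smaller share than in control, and Hopx and Gfap were higher in astrocyte-like cells while Hes5 was lower. Neuroblast-like cells were 12 of 391 aged cells (3.07%, 1.6 to 5.3) against 6.25% of control, a fold of 0.491 (0.23 to 0.979) or -3.18 points (-5.95 to -0.332). The astrocyte-like share was 13% (9.87 to 16.8) against 12.5%, a difference of 0.543 points (-3.79 to 5.06). Microglia-like cells were 51.7% (46.6 to 56.7) against 47.7%, a difference of 4.01 points (-2.57 to 10.5). With a mitochondrial limit of 30% the neuroblast-like fold was 0.518 (0.215 to 1.13), and with all barcodes, where the class also took in the cycling cells, it was 0.224 (0.124 to 0.383). With each library clustered by itself the neuroblast-like difference was -8.4 points, and without a filter the microglia-like difference turned to -5.13 points. Without a filter, mitochondria-rich barcodes without a class name counted in the total, at 65.8% of aged and 47.7% of control barcodes.

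Granule-neuron-like cells were 3.58% of aged and 6.05% of control cells, a difference of -2.47 points (-5.28 to 0.451). Oligodendrocyte-like cells were 11.8% and 8.4%, oligodendrocyte-precursor-like cells 5.63% and 4.1%, and Cajal-Retzius-like cells 8.18% and 9.38%, each with an interval of the difference that holds 0. Endothelial-like cells were 2 of 391 in aged, lower by -2.61 points (-4.54 to -0.824). Perivascular-macrophage-like cells were 0 of 391, which allows a share of up to 0.939% by the exact interval, or 0.767% by a limit of 3 counts. An unnamed cluster led by Ccl5 held 7 aged cells, 6 runner cells and 1 control cell. In aged, 16.2% of barcodes passed the mitochondrial and gene limits behind these shares, against 21.8% in control. The X-inactivation transcript Xist stood at 1430 CPM (1340 to 1530) over the aged cells used and 899 (833 to 968) over the control cells. A difference in the mix of sexes was not separated from age.

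The same 4 genes did not all follow the neuroblast-like share in aged. Dcx stood at 40 CPM (25.6 to 59.5) in aged and 36.3 (24.1 to 52.5) in control, so it was not lower over the cells used. Over all barcodes, Dcx stood at 9.85 (6.38 to 14.5) in aged and 16.7 (11.9 to 22.9) in control. Neurod1 was lower, at 23.3 (12.8 to 39.2) against 85.6 (66.2 to 109), and Sox11 was lower, at 157 (127 to 192) against 285 (249 to 326). Calb2 stood at 23.3 and 35.0, with overlapping intervals. As in the runner comparison, they were chosen after their values were seen.

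Cycling cells were 3 of 391 in aged (0.767%, 0.159 to 2.23) and 12 of 512 in control (2.34%, 1.22 to 4.06), a difference of -1.58 points whose interval holds 0 (-3.36 to 0.195). Mki67 stood at 20 CPM (10.3 to 34.9) over the aged cells used and Top2a at 8.33 (2.71 to 19.4). The 3 aged cells were microglial by their markers. They lay in the separate cluster, so the 0 cycling cells in the aged astrocyte-like and neuroblast-like classes set no limit on cycling in these lineages. With no filter, 4 of 2417 aged and 27 of 2355 control barcodes were cycling, and 1 and 11 of them were astroglial by markers. That filter setting was chosen for cycling cells after seeing the data.

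Aged astrocyte-like cells had a Gfap ratio of 2.0 (1.15 to 3.53, 39 UMIs in 51 cells against 22 in 64 cells, 505 against 253 CPM). Hopx, a marker of quiescent stem cells (chromosome 5, 77086988 to 77115121, minus strand), stood at 1.59 (1.07 to 2.37), Aqp4 at 1.52 (1.03 to 2.24) and Sox9, a transcription factor of astrocytes, at 1.75 (1.07 to 2.89). Hes5 stood at 0.349 (0.194 to 0.602, 18 against 58 UMIs), and Vim had 1 UMI against 9 (0.125, 0.00285 to 0.903). The highest genes by the interval were Ddn at 2.96 (1.63 to 5.63), Ntm at 1.8 (1.34 to 2.45), Cnn3 at 2.25 (1.29 to 4.07) and Gria2, a glutamate receptor subunit, at 1.62 (1.25 to 2.11). Ddn encodes dendrin, its mRNA is carried into dendrites, and it stood at 943 CPM in aged and 1070 in control over all barcodes and at 158 and 237 over the cells used. The remaining high genes were Dtna (1.84), Gnao1 (1.85), Gpm6b (1.39), Slc7a11 (1.91), Mid1ip1 (1.73) and Malat1 (1.08).

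Among the lowest genes in aged astrocyte-like cells were Apoe, the lipid carrier of astrocytes, at 0.822 (0.769 to 0.879), Clu, the secreted chaperone clusterin, at 0.688 (0.577 to 0.818), and Dbi, an acyl-CoA-binding protein, at 0.688 (0.582 to 0.812). Ndufc1 (0.442), Pantr1 (0.516), Pebp1 (0.479), Tspan7 (0.702), Scrg1 (0.596), Mt2 (0.787), Gpm6a (0.724) and Mt1 (0.853) were also among the 12 lowest. Sox2 (1.24, 0.645 to 2.39) and Id4 (1.05, 0.589 to 1.85) had intervals that hold 1. Nes had 1 UMI in each library, and Mki67 and Dcx had 0. Against runner instead of control, aged Cnn3, Mt2 and Mt1 turned direction, with log2 ratios of -0.0898, 0.58 and 0.38. Gfap was nearly level between these 2 libraries, with a log2 ratio of -0.0836 for runner over aged.

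As lists, BMP and Notch quiescence genes were at a median log2 ratio of 0.25 (-0.15 to 0.62) in aged astrocyte-like cells, with 6 of 8 members higher, and at -0.155 with runner as the reference. Hopx and Hes5 of this list lay on opposite sides of 1. Transport and coupling genes were at 0.10 (-0.050 to 0.28) with 11 of 13 higher and percentile 91.9. Glycolysis genes were at -0.21 (-0.44 to 0.089) with 2 of 11 higher, dissociation stress genes at -0.081 (-0.49 to 0.097), disease-associated microglia genes at -0.11 (-0.30 to 0.12), and growth factors and their receptors at 0.17 (-0.14 to 0.69). In the last list, Sparc stood at 2.41 (1.24 to 4.92) and Ntrk2, the BDNF receptor, at 0.705 (0.497 to 0.993). Ribosomal protein genes were at -0.12 (-0.26 to -0.02), turning to 0.0484 with runner as the reference, oxidative phosphorylation genes at -0.15 (-0.29 to -0.039), and mitochondrially encoded genes at 0.083 (-0.059 to 0.24). The subcluster led by Fos, Junb and Jun held 9 of 51 aged cells (17.6%, 8.4 to 30.9), against 20.3% in control. The cholesterol synthesis and neural stem cell marker lists had 4 measured members here and were not described, like the lists left out for runner.

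Aged microglia-like cells had lower glycolysis genes than control, with a median log2 ratio of -0.34 (-0.62 to -0.10), 3 of 12 members higher and percentile 0.19. Aldoa stood at a ratio of 0.575 (0.419 to 0.782) and Eno1 at 0.522 (0.354 to 0.757), while Gapdh stood at 1.01 (0.787 to 1.29). After thinning each cell to 1000 UMIs this median was 0.0123. Oxidative phosphorylation genes were lower at -0.24 (-0.32 to -0.12), with 15 of 73 higher and below each of the random lists. Dissociation stress genes were at -0.14 (-0.21 to -0.088) with 6 of 25 higher. Homeostatic genes were at 0.068 (0.048 to 0.22) and at 0.0302 with size factors, disease-associated genes at -0.042 (-0.13 to 0.050), interferon and MHC class I genes at -0.013 (-0.31 to 0.12), ribosomal protein genes at 0.0094 (-0.020 to 0.057) and mitochondrially encoded genes at 0.13 (-0.082 to 0.17). Myelin genes, products of oligodendrocytes, were at -0.68 (-1.01 to -0.19) with 1 of 6 higher, and Mbp stood at 0.632 (0.482 to 0.824). The single genes furthest from control were Rn7sk (2.96, 1.81 to 4.98), Adap2os (2.39, 1.77 to 3.26) and Hspa1a (2.3, 1.64 to 3.25) on the high side, and Ubb (0.489, 0.436 to 0.547), Gem (0.445, 0.313 to 0.624) and Hebp1 (0.362, 0.189 to 0.654) on the low side.

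**Figure D3:**
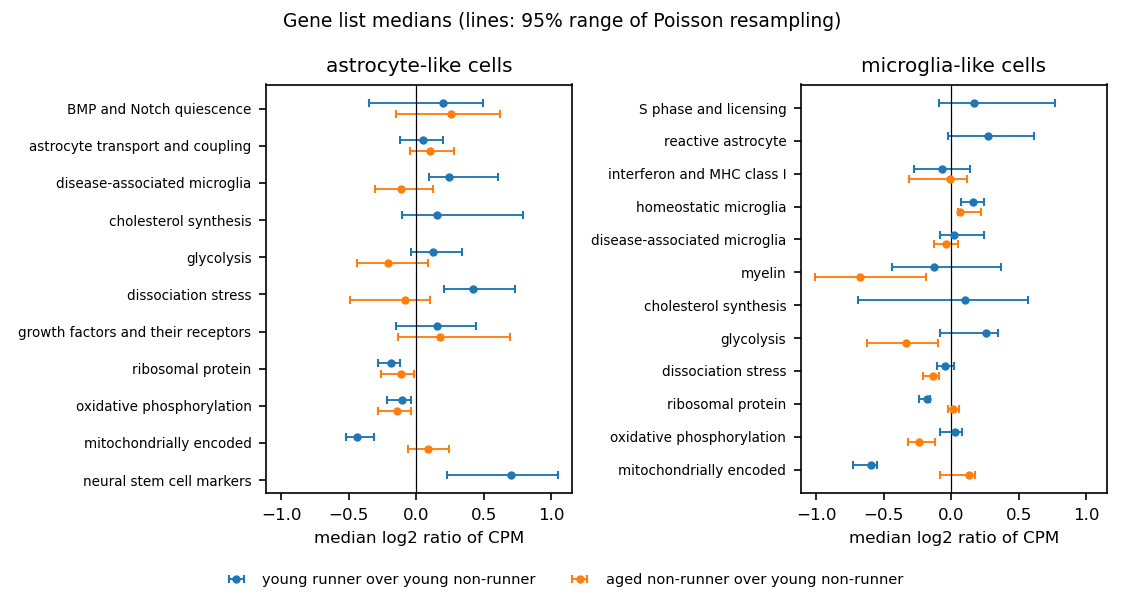
Median log2 CPM ratio (axis in log2 units) of each described gene list in astrocyte-like and microglia-like cells for runner over control and aged over control, 1 library each; points are medians and lines are 95% ranges from Poisson draws of the counts. Mitochondrially encoded genes stand at -0.44 and -0.60 in runner and at 0.083 and 0.13 in aged, for astrocyte-like and microglia-like cells.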

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

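The test of nuclear RNA in mitochondria-rich barcodes was set before its result was seen, and the tests of the neuroblast-like share and of genes outside microglia-like cells were chosen after those results were seen.

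Barcodes with at least 30% mitochondrial UMIs and no class name, left out of the comparisons, drew attention because they carried dendritically localised mRNAs such as Camk2a, Ddn and Map2. They held 6982 control, 12453 runner and 9253 aged UMIs of the list. The bound of 3 UMIs that a count of 0 allows is no yardstick here, since microglia-like cells passed it too, with 246, 210 and 136 UMIs. In the mitochondria-rich barcodes the list took 1.47% of the non-mitochondrial UMIs in 1124 control barcodes, 1.64% in 1966 runner barcodes and 1.31% in 1592 aged barcodes. It took 0.475%, 0.285% and 0.274% in granule-neuron-like cells, and 0.0718%, 0.0373% and 0.0478% in microglia-like cells. Damaged whole neurons that lost cytoplasm would keep nuclear RNA such as Malat1 and Meg3. This RNA was at most 0.031 times its percentage in granule-neuron-like cells in any library. That argues against whole damaged neurons as the main source of these unnamed barcodes. Barcodes that took a class name were not in this set, so damaged neurons that were named as neurons were not examined. Neurite fragments that hold mitochondria, and free RNA, remain open and were not tested. No biological explanation was tested.

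Neuroblast-like cells were 17.8% of the runner library, 6.25% of control and 3.07% of aged. Fewer cells of only some of 6 other classes in runner do not account for the whole gap to control. The lowest of the ratios to these classes, that to oligodendrocyte-like cells, was 1.93 times control (1.15 to 3.23). A lower yield of all 6 classes together would raise every ratio, so the ratios cannot decide on it and it stays open. The mitochondrial filter does not account for the whole gap either. The share was 5.03 times control with a 30% limit and 1.93 times (1.47 to 2.56) with all barcodes, where the class also took in cycling cells. The litter, dissection or dissociation of 1 library cannot be told apart from running, because there was 1 library per group. In aged, a lower yield of neurons of every kind stays open, since the ratio of neuroblast-like to granule-neuron-like cells was 0.83 times control (0.332 to 2.07). The ratio to Cajal-Retzius-like cells, which are also neurons, was 0.562 times control (0.253 to 1.25). More immature neurons with running and fewer with age are candidate explanations that the design names, and both stay untested.

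In runner microglia-like cells, 6 of the 6 genes furthest from control, among them Gdpd3, Gng10, Churc1, Ubb and Actb, were shifted the same way in the cells outside that class, so a shift of these genes over the whole library is a candidate explanation. Gdpd3 had 17 runner UMIs and 0 control UMIs there. The cells outside were pooled over classes whose shares differed between the libraries, such as neuroblast-like cells at 17.8% in runner and 6.25% in control. Class makeup was therefore not separated from a shift. The gap was smaller outside the class than within it for Churc1, at 1.46 (1.11 to 1.94) against 3.57 (2.49 to 5.27), Ubb, at 0.711 (0.649 to 0.781) against 0.494 (0.451 to 0.541), and Actb, at 0.691 (0.655 to 0.728) against 0.611 (0.585 to 0.639), so a shift of that size leaves part of these gaps open. In aged, 2 of 6 genes shifted the same way outside the class, Rn7sk at 3.31 (1.31 to 9.45) and Ubb at 0.462 (0.396 to 0.537), while Hspa1a was opposite at 0.289 (0.108 to 0.665). A shift over the whole aged library cannot be told apart for these genes because Adap2os and Gem had under 10 UMIs outside the class, although the count of 2 met the bound set for ruling it out, and that reason was given after the count was seen. RNA freed from microglia was not separated from such a shift, and a response of microglia to running or age stays open as untested.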

How the results depend on the processing

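The 30% mitochondrial limit, the missing filter for cycling cells, the class without the shallow cluster, naming by the first rule, subclustering without stress genes and the stem cell list were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because each group had 1 library, and its number pairs no mice. Of the share values, 118 stayed within the counting interval and 10 moved beyond it. For cycling cells the counts were 50 and 10, and for list medians 733 and 72, with 10 reversed and 46 not computed for too few members or cells. For gene levels, 170 stayed, 30 moved and 7 reversed. The other library as the reference is another comparison rather than a processing step. It gave 7 of the reversed and 25 of the moved gene levels, and 7 of the reversed and 24 of the moved list medians. A value counted as reversed by its sign, however near to level it was. The runner neuroblast-like difference was positive in each of 8 alternatives (2.93 to 13.1 points) and the aged one negative in each of 8 (-8.4 to -1.42). The astrocyte-like difference ranged from -3.02 to 0.273 points in runner and from -1.23 to 2.01 in aged. The stress list in runner astrocyte-like cells ranged from 0.28 to 0.58, and the stem cell list from 0.52 to 0.72. Subcluster resolution 0.3 left 1 astrocyte-like cluster and gave no value. Depth limits the aged neuroblast-like class of 12 cells, and Vim and Nes with at most 10 UMIs per library in astrocyte-like cells.

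With all barcodes, the microglia-like difference was -5.0 points in runner (from -10.5) and -5.13 in aged (from 4.01), and the neuroblast-like difference was 2.93 in runner (from 11.5). Mitochondria-rich barcodes without a class name then made up 47.7% of control, 59.1% of runner and 65.8% of aged barcodes. They count in the total, so they lower the shares of the other classes, and by more in runner and aged than in control. How much of each change this explains was not computed. Naming by the first rule and leaving out the shallow cluster each gave -4.75 points for runner microglia-like cells, since both remove that cluster from the class. With each library clustered by itself, the neuroblast-like difference was 7.8 points in runner and -8.4 in aged (from -3.18); the cause was not tested. With all barcodes, all 27 control cycling cells joined the neuroblast-like class, which set its percentage with proliferation genes at 36.5% (from 0%). At resolution 0.5 it was 17.9% in control; here and for the runner values of other settings the cause was not tested. In runner (from 2.92%) it was 6.74% at resolution 0.5, 10.9% with all barcodes, and 0% at resolution 2.0, with doublet calls kept and with the 30% limit. It was 7.6% with at least 2 genes, 0.585% with at least 5 and 0.595% in thinned cells.

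For lists and genes the cause was not tested. With the other library as the reference, log2 medians in runner were 0.0712 (astrocyte-like), 0.119 (oligodendrocyte-like) and 0.265 (Cajal-Retzius-like) for oxidative phosphorylation and -0.0117 for homeostatic microglia. In aged they were -0.155 for BMP and Notch quiescence, -0.583 for stress, 0.0484 (astrocyte-like) and 0.153 (oligodendrocyte-like) for ribosomal protein, 0.0117 for homeostatic microglia and 0.0252 for the disease-associated list in Cajal-Retzius-like cells. Single genes under that reference were Gfap -0.0836, Gnao1 -0.0229, Ptprs 0.205 and microglial Ubb 0.0156 in runner, and Cnn3 -0.0898, Mt2 0.58 and Mt1 0.38 in aged. Members down to 5 UMIs gave -0.0141 for the disease-associated list in astrocyte-like and -0.14 in microglia-like runner cells. The homeostatic list was 0.287 in runner with the cells' own CPM and 0.0302 in aged with size factors. In thinned aged cells, glycolysis in microglia-like cells was 0.0123 and the mitochondrially encoded list in oligodendrocyte-like cells was -0.0211.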

Other observations

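No test was run in this part, and Tac2, Igfbpl1, Igkc, Igha, Jchain, Ttr, Ccl5 and mt-Atp6 were chosen after their values were seen.

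Runner oligodendrocyte-like cells had higher lipid, sugar and myelin genes than control. Cholesterol synthesis genes had a median log2 ratio of 0.66 (0.25 to 1.12) with 10 of 12 members higher and percentile 99.6, and Fdps, an enzyme of the mevalonate pathway, stood at a ratio of 3.5 (1.11 to 17.8, 36 against 3 UMIs). Glycolysis genes were at 0.61 (0.25 to 0.92) with 9 of 10 higher, and Aldoa stood at 1.62 (1.09 to 2.5). Myelin genes were at 0.21 (0.16 to 0.44) with 12 of 13 higher, with Cnp, a myelin enzyme, at 1.48 (1.32 to 1.66). Transport genes were at 0.51 (-0.071 to 1.01), where Glul stood at 1.72 (1.47 to 2.03), dissociation stress genes at 0.17 (-0.24 to 0.55) and the disease-associated list at 0.18 (-0.055 to 0.5). Ribosomal protein genes were at -0.32 (-0.38 to -0.23), oxidative phosphorylation genes at -0.087 (-0.22 to -0.027) and mitochondrially encoded genes at -0.42 (-0.53 to -0.30). These runner cells were deeper, with a median of 2180 UMIs against 1750. The makeup of the class also differed, since a cluster of newly formed oligodendrocytes held 6 of 43 control, 10 of 119 runner and 0 of 46 aged cells, and its part in these values was not tested. In aged oligodendrocyte-like cells, myelin genes were level at -0.022 (-0.15 to 0.15), oxidative phosphorylation genes were at -0.25 (-0.39 to -0.12), ribosomal protein genes at -0.16 (-0.24 to -0.087), stress genes at 0.14 (-0.24 to 0.81), the disease-associated list at 0.26 (-0.12 to 0.41) and mitochondrially encoded genes at 0.13 (0.011 to 0.25).

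Aged Cajal-Retzius-like cells had lower energy genes, with 0 of 6 glycolysis members higher at a median of -0.85 (-1.36 to -0.37) and 10 of 60 oxidative phosphorylation members higher at -0.49 (-0.60 to -0.33). Aldoa stood at 0.448 (0.259 to 0.746). Ribosomal protein genes were at 0.099 (0.039 to 0.18), mitochondrially encoded genes at 0.20 (0.036 to 0.34), stress genes at -0.27 (-0.50 to 0.0051) and the disease-associated list at -0.31 (-1.0 to -0.02). Lower oxidative phosphorylation genes were not particular to this class, with aged medians of -0.145 in astrocyte-like, -0.241 in microglia-like and -0.252 in oligodendrocyte-like cells. Glycolysis medians were -0.338 in aged microglia-like cells and -0.209 in aged astrocyte-like cells, the latter with a range that holds 0. In runner Cajal-Retzius-like cells, stress genes were at 0.24 (0.076 to 0.41), mitochondrially encoded genes at -0.51 (-0.56 to -0.39), oxidative phosphorylation genes at -0.12 (-0.24 to -0.019) and glycolysis genes at 0.011 (-0.16 to 0.60). Within the mitochondrially encoded list, mt-Atp6 was higher in runner, at a ratio of 2.22 (1.92 to 2.59) in oligodendrocyte-like and 2.53 (2.13 to 3.03) in granule-neuron-like cells, where 11 of 14 and 8 of 13 members were lower. In runner neuroblast-like cells, 0 of 5 astrocyte transport genes were higher, at a median of -0.95 (-1.31 to -0.39), with Slc1a2 at 0.458 (0.296 to 0.731).

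Tac2, the neurokinin B precursor (chromosome 10, 127724478 to 127731768, plus strand), had 474 UMIs over the runner cells used and 6 over the control cells, and was not listed in aged. Igfbpl1 stood at 97.7 CPM in runner and 19.5 in control and was not listed in aged. In the aged library, Igkc, the kappa light chain of antibodies (chromosome 6, 70726435 to 70726966, plus strand), had 1315 UMIs, 98.1% of them in 6 barcodes, with 480 of Igha and 331 of Jchain, and Igkc and Igha were not listed in the young libraries. Ttr, a product of the choroid plexus, had 4641 UMIs in runner, 803 in control and 839 in aged, 96.6%, 98.8% and 99.2% of them in 6, 1 and 1 barcodes. Ccl5 had 154 UMIs in runner, 85.7% of them in 1 barcode, and 54 in aged, and was not listed in control. Among sex-linked genes, Xist stood at 458, 489 and 534 CPM over all control, runner and aged barcodes and Ddx3y at 29.6, 24.9 and 11.8, so X-inactivation and Y-linked transcripts were both in each library.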
